A study of Mus musculus with 47 samples.

How the data were processed

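RNA of 42 single cells and 5 bulk samples of sorted AGM cells at embryonic day 10 was analysed from the tables the authors deposited. Per the labels' protocols, sorted cells were kept on ice until lysis, deformed cells were discarded, single cells were moved by mouth pipette into lysis buffer with ERCC spike-in RNA, and cDNA was made by a published single-cell full-length method. The sort gates and the protocol of the bulk libraries beyond this are not given in the sources used here. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.7.3a and Salmon 1.1.0 and the mouse build mm10 were used; which tool made which table, the annotation release and the strand setting are not given.

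For each single cell the authors deposited gene-level TPM for 20988 genes and, for 41 of the 42 cells, isoform-level TPM for 62096 transcripts. One HEC cell of pool 2 enters the gene comparison only. Gene TPM equalled the sum over isoforms within 0.033 TPM. For each bulk library the authors deposited counts and TPM for 21866 genes. The authors made these as estimated counts per gene from reads processed with the tools above, per the submitters' processing notes, and no normalisation is recorded for them. They are taken as estimated counts since 159 genes held a value that was not whole in a library, and they were rounded to whole numbers, although whole counts had been assumed when the test was chosen. Transcript types, lengths and coordinates come from the GENCODE M21 annotation of the same build, which held 20979 of the single-cell gene identifiers, 21856 of the bulk ones and 99.8% of the transcript identifiers. TPM depends on the composition of each library, so a few abundant transcripts lower all other values.

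Bulk counts were tested with edgeR 4.0.16 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, knockout minus control, Benjamini-Hochberg adjustment, threshold 0.05), with 12714 genes tested and 3 residual degrees of freedom. The SE of a fold change was derived from its F statistic. CPM use effective library sizes. Gene lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) and with fry. Camera was run with a preset correlation of 0.01 and, beside it, an estimated correlation. With the estimated one it also uses the 3 residual degrees of freedom, where the preset uses nearly as many as genes tested. A higher p with the estimated correlation therefore does not measure correlation between genes alone. The p-values were adjusted over the 19 lists tested. The 24 lists were endothelial core, arterial and Notch, venous, hemogenic and hematopoietic, SR proteins, hnRNP and PTB proteins, core spliceosome, other splicing regulators, p53 response, S phase, G2 and M phase, interferon response, early response and heat shock, glycolysis, mesenchymal and mural, erythroid, macrophage and myeloid, megakaryocyte, epithelial and neural, Y-linked, X inactivation, cytosolic ribosomal proteins, mitochondrially encoded and spike-in. Nothing in the labels says that libraries came from separate animals or litters, so p-values measure only the spread between these libraries. Libraries of a group were no copies of each other: their counts differed by a chi-square of at least 41.5 per degree of freedom, where sampling noise gives about 1. The correlation of log2 CPM was 0.82 to 0.83 within groups and 0.77 to 0.78 between them, across genes.

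On simulated counts with the means, library sizes and fitted dispersion of the bulk comparison and 200 changed genes, the test recovered 54.7% of changes of 3 on the log2 scale and 4.1% of changes of 1, over 12317 genes, with 3 false calls. With a low dispersion it recovered 100% and 80%, over 12476 genes.

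In single cells, the difference of mean log2(TPM + 1), HEC minus AEC, was taken over all deposited cells, with SD over cells, mean TPM and the share of cells at TPM of at least 1 with an exact (Clopper-Pearson) 95% interval, which covers counting error only. List medians used members with a mean TPM of at least 1 in a group and were placed among 10000 random lists drawn from 20 bins of mean expression, as a description of these cells. Isoform usage was a transcript's share of its gene's TPM in cells with gene TPM of at least 5, for genes with at least 2 transcripts that reached this level in at least 50% of the cells of each group; 3117 genes qualified, each described by the transcript with the largest difference. With a change of 1 on the log2 scale set in 200 simulated genes, the single-cell step returned means of 0.92 and -0.90. The isoform step returned a set difference in share of 0.2 as 0.2. The shares were set without noise between cells, so the isoform check covers the arithmetic only. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 and R 4.3.3 were used.

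The gene lists, the tests, the rule for named genes and most alternatives were set before the data were examined. For bulk these were Srsf2, the 5 smallest p-values in each direction, since no gene passed, and up to 4 members per list by p. For single cells they were the 12 largest differences in each direction among genes with a mean TPM of at least 10 in a group, detection in at least 50% of cells of the higher group and pool means that did not overlap, and up to 4 members per list by size. For isoforms they were the 10 largest differences without overlap of pool means and any SR or hemogenic gene shifted by at least 20 points. Symbols of predicted genes, pseudogenes and mitochondrial genes were not ranked, and some genes that the rule selects are not reported here. Picked after their values were seen were Cdkn1a and Col1a2 in bulk, Runx1, Gfi1, Cdh5, Pecam1 and Srsf2 in single cells, the transcripts beside the named ones, Fzr1, Fasl, Gja5, Emp2 and Hlf, and the hypoxia-inducible genes, Ndrg1 and Egln3.

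Other settings tried were RLE size factors, no count filter, DESeq2 1.42.0, limma on log2(TPM + 1) with a mean TPM of at least 1 and variants of it, the replicate number as a block, each library left out, lists of 50 and 200 genes, other pseudocounts, TMM-scaled TPM, means of pool means, each pool left out, other detection and expression limits, usage from summed TPM and a minimum of 4000 genes per cell, which removed no cell. The removal of 4 dominant genes and the restriction to cells with 5500 to 7500 genes (12 AEC and 12 HEC) were added after the data were seen. So were the SR list without Srsf2 and the count of isoform genes over the 35 splits of pools. The restriction left out all of HEC pool 4 (lowest 7744 genes) and most cells of HEC pool 3 (median 7848). It kept all of AEC pool 3 (5768 to 7199 genes), so it also changed which pools were compared. The cells kept had 5510 to 7242 genes in AEC and 6264 to 7465 in HEC, so detection was brought closer but not made equal. List medians in these cells are given without random lists of their own. Splicing in the bulk libraries was not analysed here, as isoform tables were used for the single cells only.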

Results

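The series profiled polyadenylated RNA of cells sorted from the aorta-gonad-mesonephros (AGM) region of C57BL/6 mouse embryos at embryonic day 10, under a title on alternative splicing in hematopoietic stem cell formation. It held 47 samples of 2 kinds. The single-cell part held 42 wild-type cells, 18 labelled AEC and 24 labelled HEC, each sequenced as full-length cDNA. The titles placed the AEC cells in 3 pools of 8, 6 and 4 cells and the HEC cells in 4 pools of 6 cells. The bulk part held 5 libraries of sorted HEC, 3 from controls (Srsf2 f/+ or f/f) and 2 from Vec-Cre;Srsf2 f/f embryos, here called the knockout. Srsf2 encodes a serine/arginine-rich (SR) splicing factor. The bulk libraries held 4598002, 5196266 and 5181626 counts in controls 1 to 3 and 4591665 and 4970706 in knockouts 1 and 2. The single-cell tables held TPM, which keeps no depth. The number of genes at TPM of at least 1 had a median of 5711.5 in AEC cells (range 4267 to 7242) and 7562.5 in HEC cells (range 6264 to 10163).

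The first comparison asked how the transcriptome of HEC differed between knockout and control embryos. Only the knockout genotype names Vec-Cre, so an effect of Cre cannot be told apart from loss of Srsf2. The control genotype, Srsf2 f/+ or f/f, may also be mixed. Srsf2 itself (ENSMUSG00000034120, mm10 chromosome 11, 116849901 to 116853094, minus strand) was far lower in both knockout libraries. Its normalised count was 235, 204 and 219 CPM in the 3 controls and 17.2 and 20.1 CPM in the 2 knockouts, 8.52% of the control mean. The log2 fold change was -3.55 ± 0.23 (SE, n = 3 and 2), and the adjusted p of edgeR's quasi-likelihood test was 0.064. The counts cover the whole gene, and the deleted part is not given in the sources used here. Srsf2 overlaps Mfsd11 and Mettl23 on the opposite strand, so reads of these genes cannot be told apart without strand. Mettl23 had a log2 fold change of -1.91 and Mfsd11 of -0.60.

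No gene passed an adjusted p of 0.05 among the 12714 tested with edgeR, while 1662 had an unadjusted p under 0.05 (750 higher and 912 lower in the knockout), against 636 expected by chance. DESeq2 tested 21850 genes and called 853, 321 higher and 532 lower, and limma on log2(TPM + 1) tested 14368 and called 1, Srsf2. With no count filter edgeR tested 21851 genes on the same rounded counts as DESeq2 and called 4. Input therefore does not account for the 853 calls. DESeq2 leaves out genes of low mean count before it adjusts p, so its adjustment covered fewer genes than the 21850. As edgeR called no gene over its 12714 filtered genes either, the calls lay with the tool, its own filter included. Which of its steps made them was not tested. The limma setting also differed in input. The genes below are ordered by edgeR p and none of them passed. In the knockout, P4ha1, a subunit of collagen prolyl hydroxylase, was at 476 ± 34 CPM against 97.1 ± 7.5 in controls (SD, n = 2 and 3), a log2 fold change of 2.29 ± 0.15 (adjusted p = 0.064). Tmem255a (586 against 152 CPM, adjusted p = 0.064) and Clvs1 (188 against 17.3 CPM, adjusted p = 0.086) came next. They overlap Zbtb33 (log2 fold change 1.47) and Asph (0.86) on the opposite strand, with the same limit as for Srsf2. Ero1l, an oxidase of the endoplasmic reticulum, was at 218 against 37.9 CPM, and Mxi1, a partner of Max, at 363 against 97.2 CPM, both with an adjusted p of 0.14. On the lower side, Ogdh, a subunit of the oxoglutarate dehydrogenase complex, was at 199 against 444 CPM. The homeobox gene Meox1 was at 0.32 against 42.5 CPM and the collagen gene Col3a1 at 0.11 against 61.6 CPM, with 3 and 1 reads over both knockout libraries. Adjusted p was 0.14 for each of these 3 genes in edgeR. For 31.8% of the genes tested the 2 knockout libraries lay both above or both below all controls, where chance alone gives 20%.

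Among the gene lists, those of cell division were lower in the knockout than other genes. In the G2 and M phase list 21 of 22 members had a lower mean (median log2 fold change -0.95, camera adjusted p = 3.6e-05 with the preset correlation and 0.47 with an estimated one). In the S phase list it was 23 of 24 (median -0.44, adjusted p = 1.3e-04 and 0.19 in the same order). The estimated correlation was below the preset 0.01 for S phase (-0.032), p53 response (-0.020) and mesenchymal markers (-0.069). For these lists the higher p did not come from a higher correlation between genes. The degrees of freedom also differed between the settings, with 3 for the estimated correlation. For the other lists called, the estimated correlation was above the preset one, from 0.092 for endothelial core to 0.68 for glycolysis. The spindle factor gene Tpx2 was at 225 against 528 CPM, Ccnb1, which encodes cyclin B1, at 127 against 287 CPM, and the proliferation marker Mki67 had a log2 fold change of -1.20. The ribonucleotide reductase genes Rrm2 and Rrm1 were at 19.1 against 115 CPM and 98.8 against 201 CPM. These 3 G2 and M phase genes and 2 S phase genes fell when p was adjusted over the list alone. The p53 response list was higher (15 of 20 members, median 0.65, adjusted p = 0.0017, and 0.19 with an estimated correlation). Adjusted over the list alone, Eda2r (33.1 against 0.98 CPM), Plk2 (121 against 45.3 CPM) and Ccng1 (87.8 against 28.6 CPM) rose, and Aen, a nuclease gene, fell (76.8 against 162 CPM). Cdkn1a, the p53 target that encodes a cell cycle inhibitor, was at 186 against 22.9 CPM with an unadjusted edgeR p of 0.021. The p53 median was 1.15 without control replicate 2, with an adjusted p of 0.0016.

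Markers of mesenchymal and mural cells were lower in the knockout (9 of 10 members, median log2 fold change -3.09, adjusted p = 1.4e-04, and 0.19 with an estimated correlation). Adjusted over the list alone, Col3a1, Twist1 (0.10 against 8.6 CPM) and Postn (0.32 against 22.2 CPM) fell. Among the single cells described below, only 7 of the 14 listed markers reached a mean TPM of 1 in HEC or AEC cells. Bulk values cannot tell a change within HEC from a different share of other cells in the sorts. Members did not move alike, since Col1a2 was at 10.8 ± 12.4 against 12.3 ± 4.1 CPM and Postn counts in controls 1 to 3 were 7, 164 and 178. The median stayed at -3.09 with the 4 members of at most 3 counts over the knockout libraries set to that floor. With 4 of 10 members changed, the median moves only if these pass its middle. The check therefore cannot show whether counts near 0 carry the list. Without knockout replicate 1 the adjusted p of the list was 0.059, and the median was -1.86 over 8 members without control replicate 2 and -0.60 over 7 members without control replicate 3, where the list kept its call (adjusted p = 5.6e-04 and 0.0058).

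Glycolysis genes were higher in the knockout (13 of 14 members, median 0.26, adjusted p = 0.0018, and 0.73 with an estimated correlation). Adjusted over the list alone, the hexokinase gene Hk2 (78.8 against 15.4 CPM), the glucose transporter gene Slc2a1 (368 against 203 CPM), Pfkp (375 against 91.5 CPM) and Gpi1 (626 against 468 CPM) rose. The endothelial core list was also higher (18 of 24 members, median 0.26, adjusted p = 0.0079, and 0.58 with an estimated correlation), and of its members the VEGF receptor gene Flt1 rose adjusted over the list alone (651 against 241 CPM). Sox7 was at 147 against 74.3 CPM and Pecam1 at 713 against 466 CPM. Cytosolic ribosomal protein genes had a small shift in the same direction (75 of 85 members, median 0.11, adjusted p = 0.034, and 0.77 with an estimated correlation). Leaving out knockout replicate 1 gave adjusted p values of 0.079, 0.18 and 0.36 for these 3 lists, leaving out control replicate 2 gave 0.051 for endothelial core and 0.25 for ribosomal proteins, and leaving out control replicate 3 gave 0.30 for the latter. The ribosomal median was 0.060 without knockout replicate 1 and 0.16 without knockout replicate 2.

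**Figure D1:**
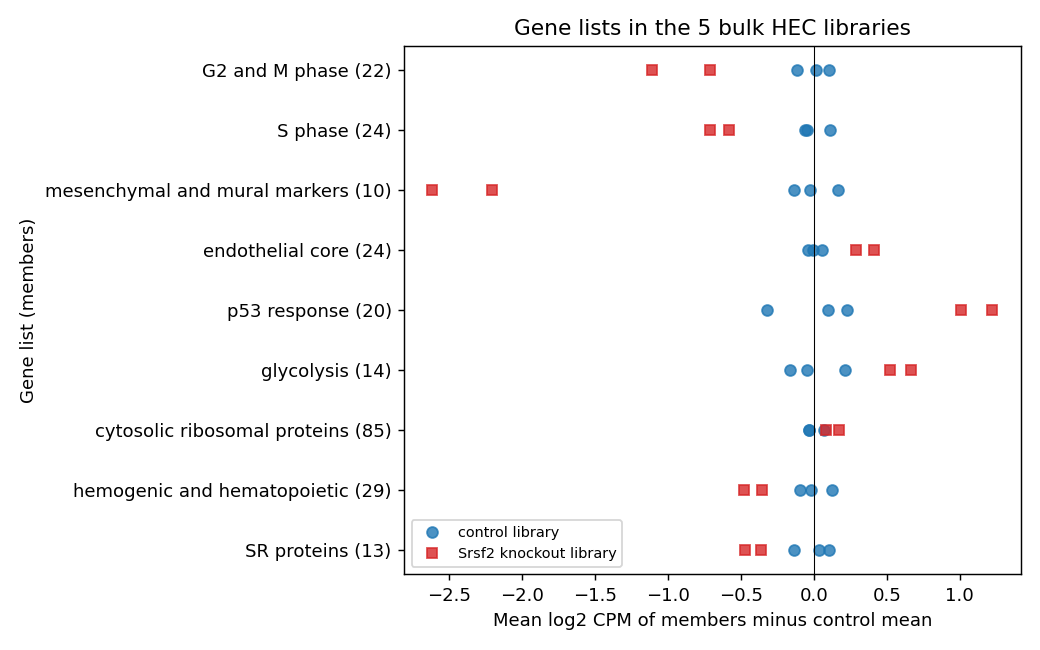
Mean log2 CPM of the members of 9 gene lists in each bulk HEC library, relative to the mean of the 3 controls (circles, control; squares, Srsf2 knockout; members tested in brackets). Both knockout libraries lie below all controls for G2 and M phase, S phase, mesenchymal markers, hemogenic genes and SR proteins (Srsf2 included), and above them for endothelial core, p53 response, glycolysis and ribosomal proteins.

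The lists closest to the function of Srsf2 were not called as groups by camera. Of 13 SR protein genes 7 were lower (median -0.06, adjusted p = 0.44, and 0.93 with Srsf2 left out of the list), and only Srsf2 passed adjusted over the list alone; Srsf5 was at 453 against 359 CPM and Srsf7 at 555 against 670 CPM. Core spliceosome genes had 25 of 36 members lower (median -0.10, and -0.20 to 0.0014 without 1 library, adjusted p = 0.44), with Eftud2 at 240 against 409 CPM and U2af1 at 60.0 against 124 CPM. Of 23 hnRNP and PTB genes 15 were higher (median 0.07, and 0.02 to 0.10 without 1 library, adjusted p = 0.51), among them Ptbp2 at 173 against 67.1 CPM and Ptbp3 at 438 against 181 CPM. Other splicing regulators had a median of 0.30 and a mean of -0.06 (adjusted p = 0.23), and the median was 0.01 without knockout replicate 2 and 0.11 without control replicate 1. Adjusted over the list alone, Clk3 rose (312 against 172 CPM), while Rbm10 (206 against 417 CPM) and Mbnl3 (0.10 against 23.2 CPM) fell.

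Hemogenic and hematopoietic genes as a list were not called either (18 of 29 lower, median -0.26, and -0.41 to -0.14 without 1 library, adjusted p = 0.33), and no member passed adjusted over the list alone. Gata2 was at 55.0 and 10.6 CPM in the knockouts against 160 ± 11.9 CPM in controls (SD, n = 3). Vav1, a signalling gene of blood cells, was at 3.4 against 39.4 CPM. Runx1, the transcription factor gene required for the endothelial to hematopoietic transition, was at 121 ± 33 against 202 ± 26 CPM (log2 fold change -0.74 ± 0.25, edgeR adjusted p = 0.32), and Kit was at 388 against 262 CPM. The self-contained test fry passed the threshold downwards for this list (adjusted p = 0.026) and for SR proteins (0.0097, but 0.51 with Srsf2 left out of the list). Of the lists called by camera, fry did not pass glycolysis (0.069) and ribosomal proteins (0.24) and passed the others in the same direction. Arterial and Notch genes had a median of 0.25 (0.02 without knockout replicate 1, 0.11 without control replicate 1) and a mean of -0.20 (adjusted p = 0.44), with Hey1 at 49.3 against 92.9 CPM and Jag1 at 0.32 against 9.2 CPM. In the venous list (median -0.02, and -0.40 to 0.04 without 1 library, adjusted p = 0.44) Aplnr (16.8 against 50.3 CPM) and Lyve1 (0.32 against 12.1 CPM) fell adjusted over the list alone. The interferon response (median 0.43, adjusted p = 0.34), early response and heat shock (-0.01, 0.55), erythroid (0.27, 0.67), macrophage and myeloid (0.37, 0.94) and mitochondrially encoded lists (0.05, 0.94) were not called. Their medians moved when 1 library was left out: interferon from 0.12 to 0.58, with camera pointing down without knockout replicate 1, early response from -0.15 to 0.14, erythroid from -2.73 to -0.09 in the 3 fits that tested it, myeloid from -0.16 to 0.39 and mitochondrial from -0.01 to 0.10. Means and medians differed in sign for the erythroid (mean -0.47), myeloid (-0.07), mitochondrial (-0.03) and early response lists (0.24). Within the early response list Ier3 rose adjusted over the list alone (73.4 against 5.5 CPM). Epithelial and neural markers had 4 members tested, too few for camera, of which Stmn2 (8.8 against 52.3 CPM) and Krt18 (22.7 against 51.5 CPM) fell and Epcam rose (7.9 against 0.80 CPM) adjusted over the list alone. With no count filter 11 of these markers were tested and the list was called lower (median -1.91, camera adjusted p = 0.015). That call was made with the preset correlation only and was not repeated with an estimated one. The megakaryocyte list had too few tested members for camera, Xist was at 79.4 against 46.3 CPM, and no Y-linked gene passed the count filter.

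A further comparison asked whether the genes that separated HEC from AEC among single cells moved in HEC without Srsf2. The 100 genes with the highest excess in HEC cells were lower in the knockout (64 of 100, median log2 fold change -0.20), and the 100 with the highest excess in AEC cells were higher (58 of 100, median 0.12), each with a camera adjusted p of 0.040. Neither call held with an estimated correlation (camera adjusted p = 0.13 for both). The estimated correlations were 0.00999 for the AEC list and 0.00959 for the HEC list, close to the preset 0.01. The loss of the calls therefore did not come from a higher correlation between genes. It came with the 3 degrees of freedom that camera uses once the correlation is estimated. The AEC list lost its call without any 1 of the 5 libraries (adjusted p from 0.063 to 0.25), with a median of 0.079 without control replicate 3 and 0.068 without knockout replicate 1. The HEC list lost it without control replicate 1 (0.075), control replicate 3 (0.057), knockout replicate 1 (0.115) or knockout replicate 2 (0.063), and had a median of -0.29 without control replicate 2 (0.032).

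The second question was how HEC cells differed from AEC cells. Each sample was a single cell and no animal was named, so each group was taken as 1 sample and no test was made. Whether a pool of cells is an embryo, a litter or a library pool is not stated, and a test over pools would need that; SD and binomial intervals describe cells only. HEC cells had more RNA of blood-forming genes and less of endothelial and arterial genes. Over the 8038 genes with a mean TPM of at least 10 in a group, the median difference of mean log2(TPM + 1), HEC minus AEC, was 0.90 as deposited, 0.68 with TMM factors and 0.71 without 4 dominant genes described below. Gene lists are therefore given beside the median of random lists of the same size and expression.

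In the hemogenic and hematopoietic list 29 of 30 genes had a higher mean in HEC cells, with a median difference of 1.89 against 0.67 for random lists, above all 10000 of them; the exception was Hlf. With TMM factors 27 of the 30 were higher. In the 12 AEC and 12 HEC cells with 5500 to 7500 genes, none of them from HEC pool 4, it was also 27 (median 1.46). Coro1a, an actin regulator of leukocytes, averaged 394 TPM in HEC and 24.03 TPM in AEC cells and was detected in 24 of 24 HEC cells (100%, exact binomial interval 85.8 to 100) and 38.9% of AEC cells (17.3 to 64.3). The transcription factor genes Mycn (125 against 11.97 TPM) and Bcl11a (79.2 against 7.2 TPM) and the receptor gene Kit (82.8 against 10.4 TPM) had the next largest differences in the list. Runx1 averaged 74.4 against 6.4 TPM and was detected in 75.0% of HEC cells (53.3 to 90.2) and 22.2% of AEC cells (6.4 to 47.6). Gfi1, a target of Runx1, was detected in 75.0% and 16.7% of cells. Outside that list, the largest differences with every HEC pool above every AEC pool belonged to Alox5ap, which encodes the activator of 5-lipoxygenase (258 against 5.6 TPM, difference 5.97, SD 2.55 in HEC and 1.80 in AEC), Mpp6 (116 against 1.5 TPM), the phosphatase gene Ptpn6 (84.2 against 0.79 TPM), Phgdh (326 against 25.3 TPM) and Lgals9 (141 against 3.0 TPM). Timm8a1, Syce2, Dek, Sfrp2, Psat1 and Slbp completed the ranked genes, with differences from 4.76 down to 4.30. Phgdh and Psat1 encode successive enzymes of serine synthesis.

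Endothelial core genes had a lower mean in HEC cells for 22 of 24 members (median difference -1.17, random lists 0.87), below all 10000 random lists, and the median was -1.10 among cells with 5500 to 7500 genes. Sox17 averaged 12.8 TPM in HEC and 59.9 TPM in AEC cells, the tight junction gene Cldn5 384 against 1192 TPM, Mmrn2 82.8 against 228 TPM and Flt1 41.9 against 89.9 TPM. Cdh5 (199 against 304 TPM) and Pecam1 (190 against 255 TPM) were detected in every cell of both groups. Arterial and Notch genes were lower for 16 of 20 members, and for 18 with TMM factors (median -0.91, random lists 0.79, below all of them), with the Notch target Hey2 at 26.3 against 110 TPM and detected in 6 of 24 HEC and 15 of 18 AEC cells, Nrp1 with a difference of -3.25, Acvrl1 at 21.3 against 90.1 TPM and Gja4 at 974 against 1979 TPM. The venous list had 4 of 5 members lower (median -0.56, percentile 0.21 of the random lists). By rank, the genes with the largest excess in AEC cells were Tmem100 (274 against 60.3 TPM, difference -5.04), Tm4sf1 (561 against 53.7 TPM, -4.90), Anxa2 (959 against 195 TPM, -4.14), Mest (1775 against 705 TPM, -3.98) and Igfbp3 (111 against 52.5 TPM, -3.97), followed by Hey2, Meg3, Ulk4, Sparcl1, Npr3, Anxa3 and Efna1, with differences from -3.85 to -3.52.

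S phase genes had a higher mean in HEC cells for 24 of 24 members (median 2.36, random lists 0.89, above all of them), and for 22 of 24 among cells with 5500 to 7500 genes (median 1.60), with the histone mRNA binding factor gene Slbp at 153 against 36.0 TPM. G2 and M phase genes were near the random lists (median 0.92, percentile 53.9), and their median was -0.05 among cells with 5500 to 7500 genes. Among splicing genes, all 13 SR genes had a higher mean in HEC cells (median 1.29, percentile 95.2), and 10 of them among cells with 5500 to 7500 genes (median 0.90), with Srsf10 at 41.4 against 13.1 TPM and Srsf2 at 318 against 154 TPM. The hnRNP and PTB (1.04, percentile 86.7), core spliceosome (1.01, percentile 60.5) and other splicing regulator lists (0.95, percentile 38.2) lay within the 95% range of random lists, as did the SR list. Glycolysis genes (1.23, percentile 99.1) and mitochondrially encoded genes (1.91, above all random lists) lay higher, and ribosomal proteins (0.65, percentile 49.0) did not. The mitochondrial median was 0.43 among cells with 5500 to 7500 genes, which hold no cell of HEC pool 4. No mitochondrial gene had separated pools, and mitochondrial genes held 0.11, 0.12 and 1.40% of TPM in AEC pools 1 to 3 and 0.61, 0.61, 1.49 and 2.10% in HEC pools 1 to 4.

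Markers of other blood cells were also seen. The macrophage and myeloid list had 8 of 8 members higher in HEC cells (median 0.75, percentile 98.9), and the lysozyme gene Lyz2 was detected in 79.2% of HEC cells (57.8 to 92.9) and 11.1% of AEC cells (1.4 to 34.7). The Fc receptor gene Fcgr3 was detected in 66.7% of HEC cells (44.7 to 84.4) and listed at 0 in every AEC cell (upper limit 18.5% for the share of cells with detection). Since AEC cells detect fewer genes, this sets no limit on the share of cells with the RNA. Megakaryocyte markers stood at a percentile of 99.9 (median 0.65). The erythroid list (0.64, percentile 82.6), p53 response (0.34, 12.2), interferon response (0.03, 2.7), early response and heat shock (1.20, 87.6), mesenchymal and mural (0.04, 13.5), epithelial and neural (0.18, 25.4) and Y-linked lists (0.12, 28.9) lay inside the random range. Xist was detected in 22.2% of AEC and 16.7% of HEC cells. Col3a1 averaged 0.71 TPM in HEC cells and 3.0 TPM in AEC cells. No spike-in row stood in the tables used here.

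**Figure D2:**
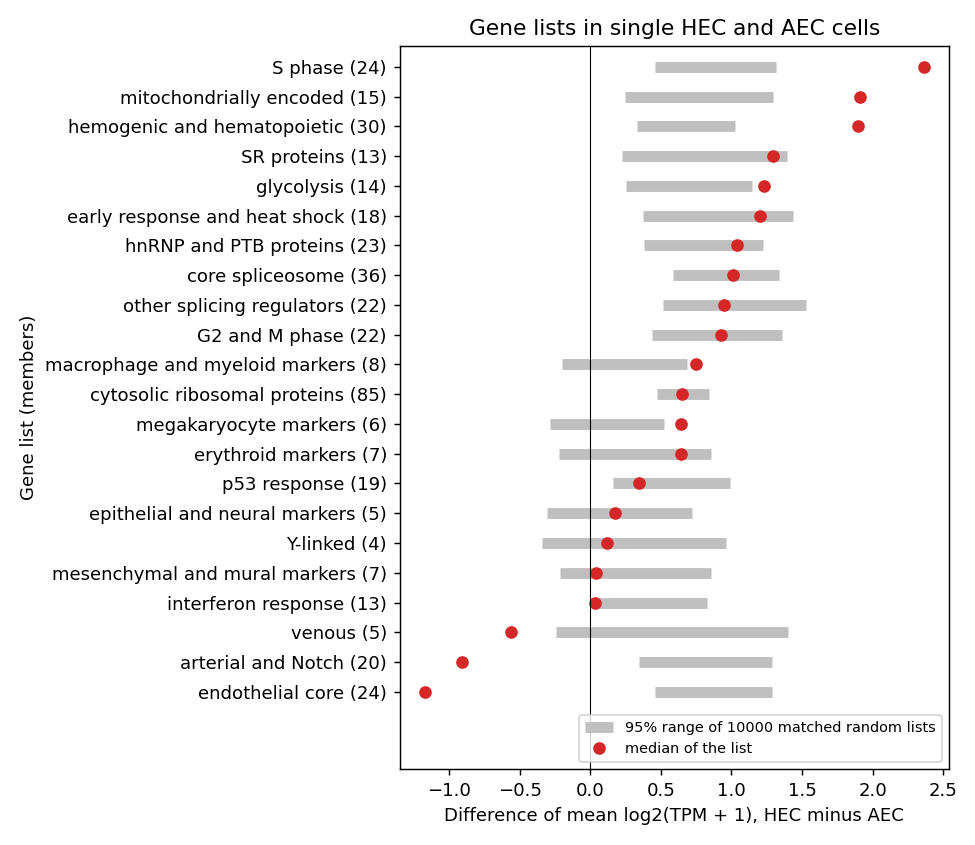
Median difference of mean log2(TPM + 1), HEC minus AEC, over the members of each gene list (red points; members in brackets) with the 95% range of 10000 random lists of the same size and mean expression (grey bars). Hemogenic and S phase genes lie above their bars at 1.89 and 2.36, and endothelial core and arterial genes below theirs at -1.17 and -0.91.

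The series also addressed isoforms. Among 3117 genes with at least 2 transcripts that could be compared, the transcript that differed most shifted by a median of 8.96 percentage points of its gene's TPM between AEC (18 cells) and HEC (23 cells with an isoform table). AEC pools differed among themselves by similar amounts, and HEC pools by less. For the same transcripts the median absolute difference was 8.55 points between an AEC and a HEC pool (12 pairs, 7.33 to 12.01), 9.67 points between AEC pools (3 pairs, 8.40 to 10.7) and 5.83 points between HEC pools (6 pairs, 5.22 to 5.93). The largest transcript shift had pool means without overlap in 386 of the 3117 genes (12.4%), against 217 to 338 genes in the other ways to split the 7 pools into 3 and 4, with the transcript chosen anew in each of 35 splits. The median shift of 8.96 points was also the largest of the 35, the others lying from 7.29 to 8.65 points. The transcripts below were selected for pool means without overlap. The retained-intron transcript Nupr1-202 held 95.6% ± 17.2 of Nupr1 TPM in 17 AEC cells and 28.9% ± 41.3 in 13 HEC cells (SD over cells). The coding Nupr1-201 held 48.5% in these HEC cells. Pool means of Nupr1-202 were uneven, at 14.1, 75.0, 3.5 and 7.4% in HEC pools 1 to 4. Of the ribonuclease inhibitor gene Rnh1, transcript Rnh1-202 held 23.1% in AEC and 86.9% in HEC cells and Rnh1-204 69.2% and 11.9%; both are annotated as coding. The chaperone gene Hsp90aa1, expressed at 828 and 884 TPM, was read in AEC cells mostly as the 711-nucleotide transcript Hsp90aa1-208 (74.8%) and in HEC cells mostly as the 2852-nucleotide Hsp90aa1-201 (6.1% in AEC and 56.0% in HEC, chromosome 12, 110691028 to 110696289, minus strand). Retained-intron transcripts of Nsun5 (Nsun5-205, 83.3% and 22.9%) and Arhgap31 (Arhgap31-202, 59.0% and 7.1%) and the noncoding Smc2-203 (69.7% and 17.1%) held larger shares in AEC cells. Pafah1b2-201 (24.01% and 79.5%) and Ppm1m-203 (25.3% and 76.2%) held larger shares in HEC cells, and Cbl-211 (86.7% and 32.4%) and Ctnnd1-205 (57.1% and 8.6%) in AEC cells. Some of these shares rest on few cells that reached the gene level, with 9 AEC cells each for Cbl, Smc2 and Arhgap31 and 10 for Ppm1m. Cbl was compared in 12 HEC cells, and the SD of Ctnnd1-205 was 51.4 points over 14 AEC cells.

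Of the hemogenic genes compared, Neurl3 was the only one to shift by at least 20 points. Its 2598-nucleotide transcript Neurl3-201 (mm10 chromosome 1, 36264597 to 36273435, minus strand) held 6.2% ± 18.9 in AEC cells and 53.03% ± 38.8 in HEC cells, and the 1206-nucleotide Neurl3-202 held the rest. Among SR genes, Tra2a-204 (4.9% and 38.2%) and Srsf5-201 (0.49% and 26.3%) were higher in HEC cells with no overlap of pool means. The retained-intron Srsf1-203 (31.1% and 7.3%) and the coding Srsf9-204 (47.7% and 25.4%) were lower with overlap. Tra2a and Srsf9 were each compared in only 9 AEC cells. Srsf2 itself shifted by -9.1 points in its retained-intron transcript Srsf2-203, and its coding Srsf2-201 held 76.8% in AEC and 82.5% in HEC cells.

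**Figure D3:**
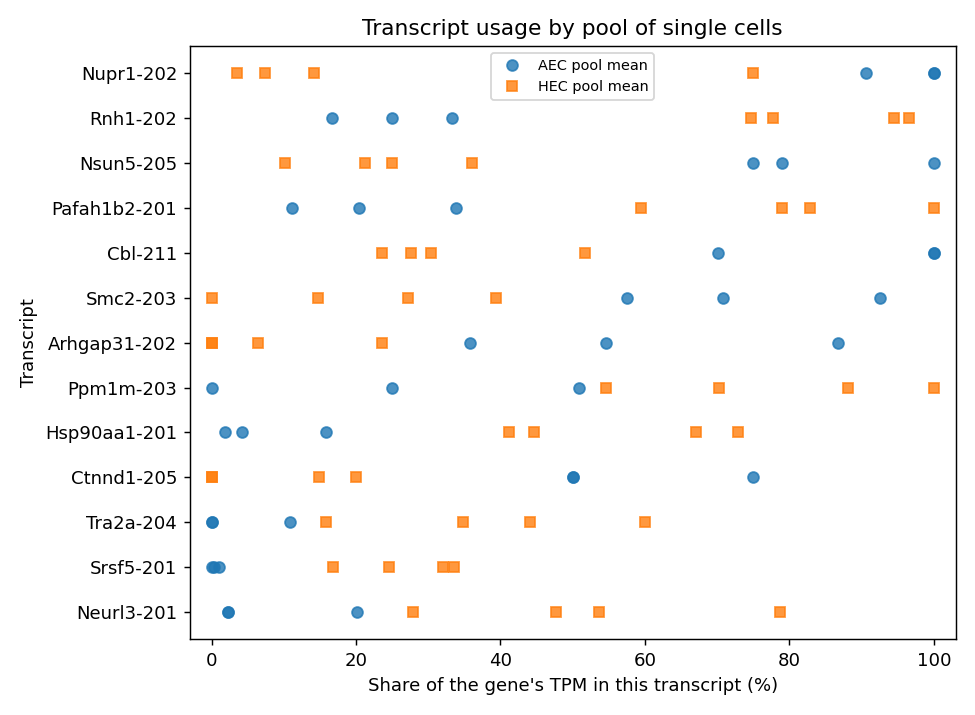
Share of a gene's TPM held by the named transcript, averaged over the cells of each pool (blue circles, 3 AEC pools; orange squares, 4 HEC pools). Transcripts were selected for AEC and HEC pool means that do not overlap; Hsp90aa1-201 averages 6.1% over AEC and 56.0% over HEC cells.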

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

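Of the alternatives, the removal of the 4 dominant genes, the restriction to cells with 5500 to 7500 genes and the SR list without Srsf2, which left the 7 list calls as they were, were chosen after seeing the data, as was the count over splits of pools. Of 1027 recomputed values, 968 kept their side of the threshold or moved by less than the spread, and 23 had the opposite sign. All 23 were medians of 5 single-cell lists inside the range of random lists, namely, with the value reported and the lowest one, G2 and M phase (0.92 to -0.12), interferon (0.03 to -0.12), mesenchymal (0.04 to -0.24), epithelial and neural (0.18 to -0.40) and Y-linked (0.12 to -0.17). That only values outside that range count as reversed was settled after these were seen. In bulk, 16 of 169 list medians changed sign, over 7 lists that camera had not called, SR proteins (0.01 without control replicate 3) and core spliceosome (0.0014 without knockout replicate 2) among them. The number of bulk genes called, 0 with edgeR, was 4 with no filter, 853 with DESeq2, 1 with limma on log2(TPM + 1) and 1 with log2(TPM + 0.1). It was 0 with RLE size factors, with limma on TPM with no filter and without any 1 control library. The 853 calls lay with the tool, its own filter before adjustment included, since edgeR used the same counts and called few or no genes with and without a filter. Which step of the tool made them was not tested. Srsf2 kept its fold change and passed the threshold with no filter (-3.55, adjusted p = 0.034), with DESeq2 (-3.56, 2.9e-30), with limma on log2(TPM + 1) (-4.05, 0.035) and on log2(TPM + 0.1) (-4.11, 0.043), against adjusted p values of 0.061 to 0.53 in the other settings. The number of gene lists called by camera, 7, was 0 with an estimated correlation and 3 to 7 without 1 library, the 3 without knockout replicate 1 being G2 and M phase, S phase and p53 response.

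The median log2 fold change of the 100 AEC-high genes, 0.12, was 0.0675 to 0.17 without 1 library, 0.12 with an estimated correlation, 0.22 with 50 genes (adjusted p = 0.018) and 0.15 with 200 genes (0.011). That of the 100 HEC-high genes, -0.20, was -0.29 to -0.18 without 1 library, and -0.20 with an estimated correlation, with 50 genes (0.13) and with 200 genes (0.011). Both lists missed the threshold with an estimated correlation and in most of the fits with 1 library fewer. Replicate numbers 1 and 2 occur in both bulk groups, but nothing says that they pair, and the differences between replicates 1 and 2 of each group correlated at only 0.029 across genes. With the replicate number as a block, edgeR called 0 genes, 6 lists kept their call (ribosomal proteins did not, adjusted p = 0.28), and the 2 lists of population genes had medians of 0.087 and -0.24 with adjusted p values of 0.17 and 0.12. The median usage difference, 8.96 points, was 9.13 to 11.3 points without 1 pool, highest without AEC pool 1. Single-cell TPM keeps no depth, so a transcript missing from a cell cannot be told from one that was not sampled.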

Other observations

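The tests in this part were chosen after the data were seen, and the if-and-if-not bounds of those on cells with 5500 to 7500 genes were written before their results were known.

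The bulk knockout libraries also had higher counts of genes that respond to low oxygen. Of 30 hypoxia-inducible genes written down after the first look at the data, none of them in the glycolysis list, 27 were tested once the 50 genes with the smallest p were left out, and 27 of 27 had a higher mean in the knockout (median log2 fold change 1.22). As the list was picked after values were seen, this count tests nothing. Pdk1, which limits entry of pyruvate into mitochondria, was at 406 against 130 CPM, the autophagy receptor gene Bnip3l at 506 against 297 CPM, Vldlr at 656 against 172 CPM and the peptide hormone gene Adm at 95.1 against 8.99 CPM. The collagen-modifying genes P4ha2 (121 against 8.86 CPM) and Plod2 (196 against 30.0 CPM) were higher too. Outside the 30 genes, Ndrg1 was at 86.4 against 1.93 CPM and the prolyl hydroxylase gene Egln3 at 101 against 14.7 CPM.

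For the higher glycolysis genes of the knockout (camera adjusted p = 0.73 with an estimated correlation), library size was looked at first. The ratio of mean total counts, knockout over control, was 0.96, so the libraries were of similar size. CPM already scale by library size, so this ratio cannot decide anything about the glycolysis list. A wider hypoxia-type program stays open. Camera over the 27 genes gave p = 0.0038 upwards with an estimated correlation, but on genes picked after their values were seen, so this p does not support it. For stress during sorting, a negative median of the early response and heat shock list had been written as speaking against it, after the data were seen. The median was -0.012, with 8 members higher and 10 lower, and its sign changed when single libraries were left out. It therefore decides nothing, and stress during sorting stays open. The labels give no sort dates, so such stress cannot be told apart from genotype. Whether Srsf2 loss, embryo size or oxygen supply could underlie the pattern was not tested.

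A few genes took an unusual share of the single-cell TPM. Fzr1, Fasl, Gja5 and Emp2 together held 23.5% ± 13.8 of TPM in AEC cells and 5.18% ± 4.70 in HEC cells (SD over 18 and 24 cells), up to 51.0% in 1 AEC cell. Their mean TPM in HEC cells was 27.9, 75.0, 332 and 240 times that in the bulk HEC controls, while the ratio was 0.79 for Runx1, 0.78 for Kit and 5.14 for Cdh5. These ratios rest on uneven pools, since the 4 genes held 3.87, 8.36, 7.81 and 0.687% of TPM in HEC pools 1 to 4. Emp2 averaged 731, 5947, 8283 and 183 TPM in these pools, against 15.8 TPM in bulk. Of Gja5 TPM, 98.4% in AEC and 99.4% in HEC cells lay on the 405-nucleotide transcript Gja5-202 (chromosome 3, 97032416 to 97050873, plus strand). Hlf averaged 5336 TPM in AEC and 1258 TPM in HEC cells, 99.5% and 83.5% of it on the noncoding Hlf-203.

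Most genes had a higher mean log2(TPM + 1) in HEC than in AEC cells, and the dominant genes could account for part of this. Without them and with TPM rescaled, the median difference was 0.71 in place of 0.90, which argues against these genes as the whole cause. Among the 783 other genes detected in every cell it was 0.29 in place of 0.62, so the shift of these genes fell further. In cells with 5500 to 7500 genes and without the 4 genes, the median over the wider set of genes was 0.34 (0.18 to 0.41 with 1 pool left out). This lay between the bounds of 0.2 and 0.5 set beforehand. Fewer detected genes in AEC cells may therefore contribute. How far cannot be told apart from the cell population, or from the absence of HEC pool 4 and most of HEC pool 3 among these cells.

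Protein-coding transcripts held 72.9% ± 3.8 of TPM in AEC cells and 78.5% ± 2.2 in HEC cells once the 4 dominant genes were left out, and retained-intron transcripts 8.92% ± 0.98 and 7.47% ± 0.78. With the 4 genes kept, retained-intron transcripts held 7.01% ± 1.19 and 7.11% ± 0.75, so their excess in AEC cells was seen only without these genes. The difference of the coding share was 5.63 points without and 4.80 points with the 4 genes, so the shares taken by these genes are argued against as its cause. Among cells with 5500 to 7500 genes it was 4.29 points, above the bound of 4 points set against an effect of detection. With 1 pool left out it was 1.99 to 5.41 points, a spread that crosses this bound and that of 2 points set for such an effect, so the effect stays open. Library quality and cell population cannot be told apart here, since pools were nested in the groups. The mean transcript length weighted by TPM was 1457 ± 73 nucleotides in AEC and 1472 ± 76 in HEC cells.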
